A study of Mus musculus with 14 samples.

How the data were processed

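Total RNA of microglia isolated with magnetic beads from mouse brain was sequenced in 14 libraries. Per the labels' protocols, RNA was taken up in TRIZOL and libraries were made with a universal RNA-seq kit for Illumina, and the labels do not state strand. Per the submitters' processing notes, reads went through FastQC 0.11.9, cutadapt 4.4, STAR 2.7.10b and featureCounts 2.0.1. The notes name hg38, a human build, while the gene IDs in the table are those of mouse. The deposited values are TPM per gene, which the authors made by dividing reads by gene length and scaling each library to a total of 1000000. The table held 41739 genes, of which 12553 were at 0 in all 14 libraries. Gene names came from the reference table for 41588 IDs, and 151 had none. No coordinates are printed, as the build is uncertain.

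Depth was recovered from the TPM values. With exon-union lengths of GENCODE M21 from the reference, the values times length were whole multiples of 1 unit per library, within a tolerance of 0.02 reads, for 98.4% to 98.6% of values, and 41273 genes (99.0%) were whole in all libraries. The totals so obtained are estimates, since the length table may not be the one the authors used. In simulated libraries of 29158 genes the step recovered 100% of the reads.

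Libraries were placed in 4 groups by genotype and treatment, and the comparisons were KO to WT under PBS, KO to WT under LPS, LPS to PBS in WT, LPS to PBS in KO, and the interaction of both. The log2 of TPM plus 1 was modelled with limma 3.58.1 in R 4.3.3, with 4 group means, an intensity trend and Benjamini-Hochberg adjustment over the 18724 genes with a TPM of at least 1 in at least 3 libraries. A gene was called at an adjusted p under 0.05, and every adjusted p of a single gene is from this limma test unless another is named. Rises and falls in the text are called genes. Fold changes of log2(TPM + 1) are smaller than ratios of TPM where values are low. The labels do not say that the libraries of a group came from separate animals, so p-values measure only the spread between libraries. Every KO library and no WT library carried Cre, so effects of Cre or of the Tmem119 allele are not separated from those of Rheb. Tests of single values are exact two-sided permutation tests.

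The comparisons, the gene lists, the rule for naming genes and the first set of other settings were chosen before the data were examined. Lists of at least 5 measured members were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over 33 lists. They were lysosome, V-ATPase, autophagy, mTORC1 and its regulators, ATF4 targets and amino acid metabolism, branched-chain amino acid catabolism, cholesterol and fatty acid synthesis, lipid efflux and storage, glycolysis, pyruvate dehydrogenase and TCA cycle, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, nucleotide synthesis, ribosomal proteins, unfolded protein response, interferon response, NF-kB and inflammatory mediators, homeostatic and disease-associated microglia, antigen presentation, cell cycle, and immediate early and dissociation genes. The others were markers of border macrophages, monocytes, neutrophils, T and NK cells, B cells, astrocytes, neurons, oligodendrocyte lineage, endothelial and mural cells, choroid plexus and ependyma, and erythroid cells.

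Genes were named by rule. Named were the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 TPM in the higher group, no overlap between the groups and a gene symbol other than a model name. Up to 3 called members per direction of each list were eligible, or 1 value where none was called, and the text gives part of these. Rheb, Rhebl1, Mtor, Rptor, Tmem119, Lamp1, Lamp2, Tfeb, Sqstm1, Ctsb, Tnf and Il1b were always eligible. Where no gene was called, the 3 with the smallest p per direction are given as values. Some results that the rule covers are not reported here. Genes named outside the rule are said to be chosen after their values were seen.

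The first set of other settings held pseudocounts of 0.1 and 5, no filter and a filter at a TPM of 5, median-of-ratios scaling, quantile normalisation, removal of mitochondrial, ribosomal protein and haemoglobin genes, no intensity trend, robust variance moderation, library weights, a fit of the compared groups alone, an added fold limit, a block by replicate number, and leaving out each library in turn. After seeing the data, further settings were added: leaving out WT_PBS_914 and KO_LPS_3, removing Gm23935, leaving out genes under 200 nt, leaving out X and Y genes, voom on the recovered reads, the average KO effect over both treatments, and exact permutation of list means. Leaving out genes on X and Y moved no count by more than 1.5 times. Genes with near-identical copies, such as ribosomal protein genes with pseudogenes, H2-DMb1 and H2-DMb2, and haemoglobin genes, share reads, and genes overlapping on opposite strands are uncertain as strand is not stated.

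The limma step was tested on simulated data drawn from the real means. For KO to WT under PBS (18546 genes), 19.4%, 52.3% and 75% of genes changed by 1.5, 2 and 4 times were found, with 11 unchanged genes called. Under LPS (18545 genes) the shares were 15.2%, 54.5% and 63.6% with 5 unchanged called. For LPS in WT (18620 genes) they were 21.5%, 59.4% and 75.4% with 1, in KO (18549 genes) 12.3%, 50% and 71.2% with 8, and for the interaction (18495 genes) 4.84%, 25.4% and 53.1% with 4. No changed gene was called in the wrong direction. The lysosome list, moved by 1.3 times, was called in all 5 comparisons, with at most 1 of 32 other lists called. That low count does not carry over to the real libraries. There, splits other than the real one called 6 to 13 lists for KO to WT under PBS and 9 to 26 under LPS, at the preset correlation. The simulation therefore does not show how many list calls chance gives in the real data. Figures were drawn with matplotlib 3.10.9 under python 3.11.15.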

Results

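RNA was sequenced from microglia, the resident macrophages of the brain, purified with magnetic beads from adult mice. Rheb encodes a small GTPase that activates the growth-controlling kinase complex mTORC1. Mice with floxed Rheb alleles alone are called WT here, and mice that also carried a tamoxifen-inducible Cre recombinase expressed from Tmem119, a microglial gene, are called KO. At 8 weeks of age, after tamoxifen, they received daily intraperitoneal injections for 4 days of PBS or of LPS, the bacterial endotoxin, at 1.0 mg/kg. The 14 libraries comprised 3 WT PBS, 3 KO PBS, 4 WT LPS and 4 KO LPS. The reads behind the values, recovered from the table and given in M (mega) reads, ranged from 8.00 M in KO_LPS_4 to 32.3 M in WT_LPS_1. Among the other libraries, the PBS libraries held 15.7 to 20.7 M reads, the KO LPS libraries 16.6 to 21.8 M and the WT LPS libraries 19.3 to 27.5 M. Within groups, libraries correlated across genes with Pearson's r of 0.939 to 0.976.

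Several transcripts set whole libraries apart. The design text describes female mice. The Y-linked gene Ddx3y stood at 111 to 146 TPM in the 6 PBS libraries, where Xist, the transcript that silences an X chromosome in females, stood at 0.147 TPM or less. In the 8 LPS libraries, Xist stood at 255 to 329 TPM in WT and 354 to 574 TPM in KO, without overlap, and Ddx3y at 0.270 TPM or less. The other Y-linked genes Eif2s3y, Uty and Kdm5d parted the libraries in the same way. The PBS libraries thus carried the transcripts of males, against the design text, and the LPS libraries those of females. Sex and treatment therefore ran together in every library of both genotypes, and no LPS to PBS value can separate them. Both KO to WT comparisons lie within one sex. Growth hormone (Gh) reached 78126 TPM in WT_PBS_914 and 19672 TPM in KO_LPS_3, and at most 1.90 TPM in the other 12 libraries. Prolactin (Prl) reached 2646 and 7067 TPM in these libraries, and Pomc 5368 and 4724 TPM. Other endocrine transcripts stood at lower levels in further libraries: under PBS, Cga was listed at 45.9, 33.1 and 32.2 TPM and Chga at 131, 91.0 and 143 TPM in WT_PBS_904, WT_PBS_913 and KO_PBS_912, against 0 TPM and 0.196 TPM or less in KO_PBS_911 and KO_PBS_915, which is uneven between the genotypes. Under LPS, apart from KO_LPS_3, Cga reached at most 13.5 TPM and Chga 31.3 TPM. Gm23935, a feature of under 200 nt annotated as a microRNA, took 0.0566% to 0.248% of the TPM total in PBS libraries and 4.04% to 15.4% in LPS libraries, the highest share being in WT_LPS_4. This share also parted the treatments in full. The labels give 1 preparation for all libraries, but a difference in preparation between PBS and LPS libraries cannot be told apart from treatment in any LPS to PBS value.

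**Figure D1:**
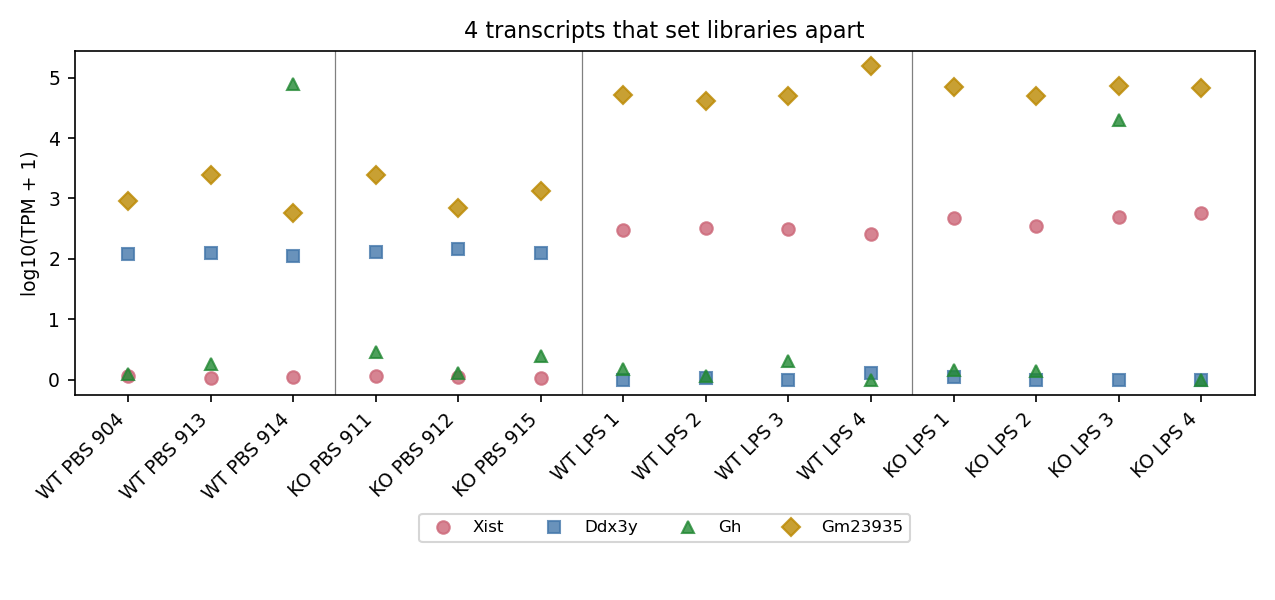
Level of Xist, Ddx3y, Gh and Gm23935 in each of the 14 libraries, as log10(TPM + 1), with lines between the groups. Ddx3y lay at 111 TPM or above in each PBS library and Xist at 255 TPM or above in each LPS library, and Gh was abundant in WT_PBS_914 and KO_LPS_3.

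Rheb mRNA was lower in the KO groups. Under PBS it stood at 32.1 ± 2.39 TPM (SD, n = 3) in WT and 18.2 ± 1.43 TPM (n = 3) in KO, 56.7% of the WT level, and every KO library lay below every WT library. The log2 fold change was -0.79 (adjusted p = 0.0163, limma), and the exact two-sided permutation test gave p = 0.1, the smallest that 3 libraries against 3 allow. Under LPS, Rheb stood at 30.8 ± 3.83 TPM (n = 4) in WT and 22.7 ± 2.43 TPM (n = 4) in KO, 73.9% of WT, and did not pass the test (log2 fold change -0.42, adjusted p = 0.11). There the highest KO library, at 25.5 TPM, lay above the lowest WT library, at 25.1 TPM (exact permutation p = 0.0571, where 0.0286 is the smallest possible). The PBS call was lost without KO_PBS_911 (log2 fold change -0.72, adjusted p = 0.0946) and likewise without KO_PBS_912, WT_PBS_913 or WT_PBS_914, at -0.82, -0.78 and -0.74. The LPS difference passed with median-of-ratios scaling (-0.51, adjusted p = 0.0407). Rhebl1, the paralog of Rheb, stood at 3.79 ± 1.28 TPM in WT and 3.91 ± 1.56 in KO under PBS, and 2.88 ± 1.31 and 4.08 ± 0.473 under LPS, neither pair past the test.

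Tmem119, a marker of homeostatic microglia and the gene that drives Cre in the KO mice, fell in KO under both treatments. It went from 3467 ± 482 to 2114 ± 97.2 TPM under PBS (log2 fold change -0.70, adjusted p = 0.0389) and from 1733 ± 117 to 844 ± 116 TPM under LPS (-1.04, adjusted p = 0.00857), with no overlap between the groups in either. Mtor and Rptor, which encode the kinase and the scaffold of mTORC1, had log2 fold changes of 0.00 and 0.03 under PBS and 0.06 and -0.13 under LPS, none past the test. In the list of mTORC1 and its regulators, no member of 50 was called under either treatment, and adjusted over the list alone 1 rose under LPS. That member was Rps6 (log2 fold change 0.66, adjusted p = 0.0553 over all genes, limma), itself a ribosomal protein gene. Of the other genes fixed in advance, Lamp1 and Lamp2 (lysosomal membrane proteins), Tfeb (a regulator of lysosomal genes), Sqstm1 (an autophagy receptor) and Ctsb (a lysosomal protease) did not pass the test in either comparison. The smallest adjusted p among these was that of Ctsb under LPS, with a log2 fold change of -0.49 ± 0.11 (SE, 4 libraries per group, adjusted p = 0.0722). The cytokine genes Tnf and Il1b did not pass either: Tnf stood at 14.7 ± 2.89 TPM in WT PBS and 50.7 ± 33.1 in KO PBS.

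**Figure D2:**
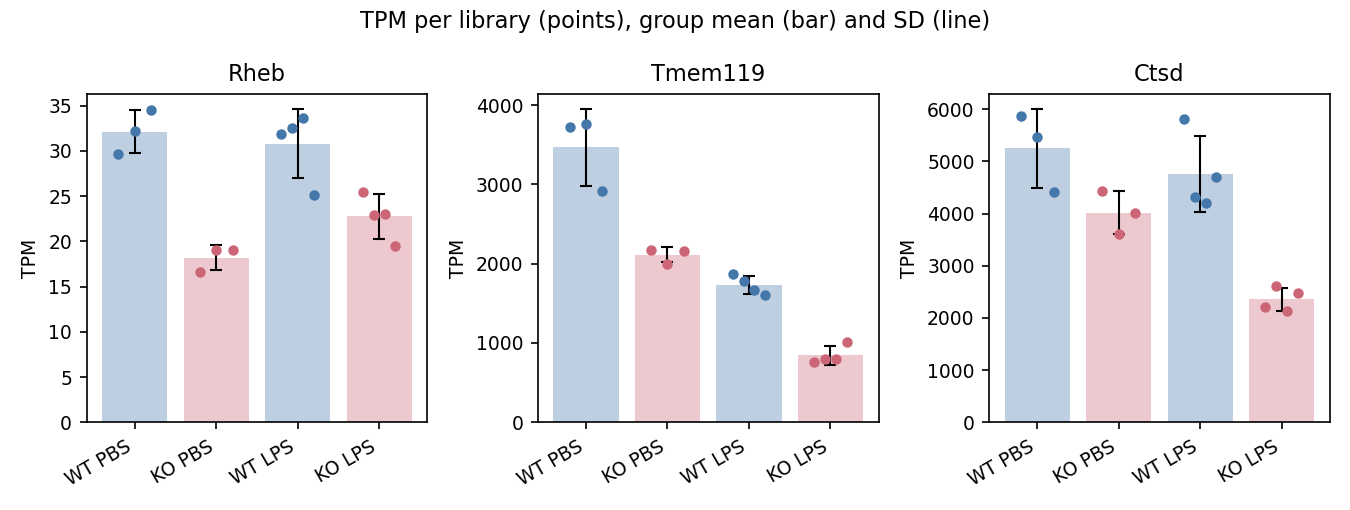
TPM of Rheb, Tmem119 and Ctsd (cathepsin D) in each library (points), with the mean (bar) and SD (line) of each group of 3 or 4 libraries. Rheb and Tmem119 were lower in KO than in WT under both treatments, with the Rheb difference under LPS short of the test, and Ctsd fell in KO under LPS from 4761 to 2358 TPM.

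Without LPS, the KO to WT comparison asks what loss of Rheb does to resting microglia. All 78 ribosomal protein genes measured had a positive log2 fold change, with a median of 0.61. Of these 78, 10 rose over all genes tested and 74 adjusted over the list alone, such as Rpl12 (0.96), Rps28 (0.88) and Rplp2 (0.82). Receptor and inflammatory genes were among those that rose: Hcar2, a receptor for hydroxybutyrate, went from 4.82 ± 1.3 to 17.3 ± 4.09 TPM, Gpr84, a receptor for medium-chain fatty acids, from 42.4 ± 3.80 to 123 ± 12.2 TPM, and Siglecf, a sialic acid receptor, from 27.9 ± 3.62 to 69.5 ± 0.692 TPM. Genes that fell included H2-Ob, a chaperone subunit of antigen presentation (27.4 ± 1.19 to 10.6 ± 1.24 TPM), Arrdc3 (50.5 ± 8.19 to 20.8 ± 1.35), and the clock-output transcription factors Hlf (-1.48) and Dbp (-1.19). By limma, 191 of 18724 genes were called, 149 higher and 42 lower in KO. A fit of the compared groups alone called 109, of which 57 were among the 191, and without both WT_PBS_914 and KO_LPS_3 the calls were 19, of which 17 were among them. The count rested on each library: it fell to 8 without KO_PBS_911, 10 without KO_PBS_912, 39 without KO_PBS_915, 40 without WT_PBS_914, 45 without WT_PBS_913 and 50 without WT_PBS_904.

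Among the other genes that rose under PBS were Il1a (log2 fold change 1.06) and Icam1 (0.72) of the list of NF-kB and inflammatory mediators, which held 3 called members of 58, with Gpr84 (1.52) as the third. The transcription factor gene Myc (1.08) rose as the called member of the immediate early list, Csf3r, the receptor for G-CSF (0.60), in the neutrophil list, Nagpa, an enzyme of lysosomal targeting (0.58), in the lysosome list, Gart, of purine synthesis (0.55), in the nucleotide synthesis list, and Mpc1, a mitochondrial pyruvate carrier subunit (0.46), in the pyruvate dehydrogenase and TCA cycle list. In the antigen presentation list, H2-DMa (0.89) and Tap2 (0.47) rose. Homeostatic markers went both ways, Olfml3 rising by 0.70 and Tmem119 falling by 0.70 on the log2 scale. Cd22, an inhibitory sialic acid receptor, fell (-1.33), as did Angptl7 (-1.72), Ctla2b (-1.40), Mcub, a subunit of the mitochondrial calcium uniporter (-1.21), and the autophagy gene Gabarapl2 (-0.38). Among short RNAs, Mir1938, Mir6928, Snord42b and Snord23 were listed at 0 in all WT PBS libraries and at means of 34.4, 22.2, 8.67 and 6.43 TPM in KO, Snord104 rose by 1.13, and Mir3093 was listed at 0 in KO and at 7.74 TPM in WT.

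By camera with a preset correlation of 0.01, 13 of 33 fixed lists were called under PBS, and none remained with an estimated correlation, where the smallest adjusted p was 0.895. The lists called higher in KO were the ribosomal proteins (adjusted p = 0.895 with an estimated correlation), the unfolded protein response (median 0.19, 0 of 24 called), the NF-kB list (median 0.18) and the immediate early genes (median 0.27). The same adjusted p of 0.895 with an estimated correlation held for those 3. Lists of other cell types were called lower: endothelial and mural (median -0.68, 0 of 20 called), monocyte (-0.53, 0 of 15), neuron (-0.63, 0 of 11), neutrophil (-0.57, 0 lower of 18) and B cell markers (-0.37, Cd22 called of 10), each with an adjusted p = 0.895 with an estimated correlation. Without WT_PBS_914, the library rich in pituitary hormone transcripts, the medians of the monocyte, neuron, neutrophil and B cell lists were -0.08, -0.23, 0.02 and -0.16. Without WT_PBS_904, those of neuron and neutrophil markers were -1.04 and -0.99, and that of the immediate early genes ranged from 0.12 (without KO_PBS_911) to 0.49 (without WT_PBS_913). Pecam1, an endothelial adhesion protein, stood at 89.5 ± 18.2 TPM in WT and 43.3 ± 17.0 in KO, not past the test. Cell cycle (-0.26, 0.03 without WT_PBS_914), interferon response (-0.21), ATF4 targets and amino acid metabolism (-0.14, -0.08 without WT_PBS_904) and cholesterol and fatty acid synthesis (-0.12) were also called lower with no member called. Their adjusted p was 0.895 with an estimated correlation, and 0.903 for the interferon response. Lysosome, V-ATPase, homeostatic microglia and mTORC1 lists were not called.

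**Figure D3:**
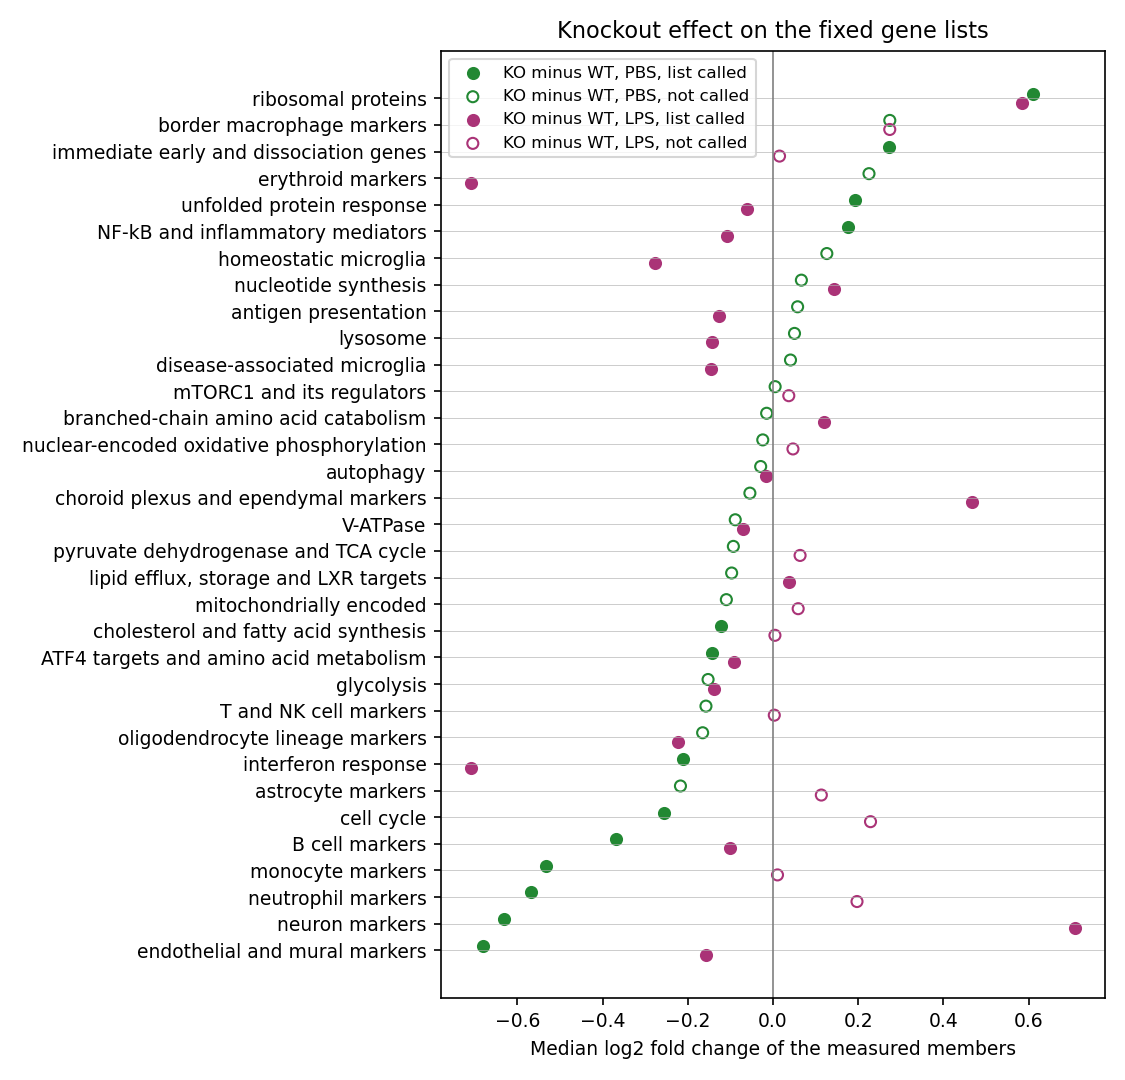
Median log2 fold change of the measured members of each of the 33 fixed gene lists, KO minus WT under PBS (green) and under LPS (purple), with filled points for lists called by camera at a preset correlation of 0.01. The ribosomal protein list lay highest under PBS at 0.61 and stood at 0.59 under LPS, and no list was called with an estimated correlation.

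Under LPS, the same comparison asks how the KO genotype changes microglia exposed to endotoxin, with Rheb itself short of the test there. Ribosomal protein genes were higher again, with 78 of 78 positive and a median of 0.59. Of them 21 rose over all genes tested and 74 adjusted over the list alone, among them Rpl12 (1.05) and Rps18 (0.90). Among the genes that fell, Ctsd, encoding cathepsin D, went from 4761 ± 731 to 2358 ± 220 TPM, Cst3, a secreted inhibitor of cathepsins, from 11874 ± 1382 to 5414 ± 440 TPM, and Crybb1, a homeostatic marker, from 387 ± 93.6 to 179 ± 33.2 TPM. Il6, an inflammatory cytokine gene, rose from 10.9 ± 2.45 to 22.2 ± 2.38 TPM, and Epha2, a receptor tyrosine kinase, from 26.3 ± 4.32 to 56.6 ± 8.18 TPM. By limma, 93 genes were called, 48 higher and 45 lower. A fit of the compared groups alone called 0 (1827 had an unadjusted p under 0.05), as did a block by replicate number (1364), and without both WT_PBS_914 and KO_LPS_3 the calls were 8, of which 7 were among the 93. With median-of-ratios scaling, which moved the median of all genes from 0.07 to -0.01, the calls were 172, 27 higher and 145 lower. The count was 18 without KO_LPS_3, 33 without WT_LPS_1, 41 without KO_LPS_2, 42 without WT_LPS_2 or without WT_LPS_4, and 50 without WT_LPS_3.

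Other genes called under LPS included H2-DMb2 (1.28; its reads are hard to separate from those of its near-copy H2-DMb1) and H2-DMa (0.64), which load peptides on class II molecules, and Arsb, a lysosomal sulfatase (0.64), which rose, and Rpl32 (0.83) and Snord42b (2.52), also higher. Those that fell were Cox6a2 (-1.93), Cd22 (-1.50), Kcnj9 (-1.44), Tbx6 (-1.42), Cdc42ep3 (-1.22), Anapc15 (-1.14), Serpine2 (-0.78) and the tetraspanin Cd63 (-0.59). By camera with the preset correlation, 21 of 33 lists were called, and none with an estimated correlation. Of the homeostatic microglia list (median -0.28), 5 of 48 fell over all genes and 15 adjusted over the list alone (adjusted p = 0.321 with an estimated correlation). Of the lysosome list (median -0.14), Ctsd and Cd63 fell and Arsb rose among 78, and adjusted over the list alone 14 fell and 2 rose (adjusted p = 0.426 with an estimated correlation). The disease-associated microglia list (median -0.14) held Ctsd and Cd63 as its called members of 33 (adjusted p = 0.321 with an estimated correlation), and its median was -0.06 without KO_LPS_4. Interferon response genes were lower as a list, with a median of -0.71 and 57 of 59 negative but no member called (adjusted p = 0.321 with an estimated correlation), and the median was -0.39 without WT_LPS_3. Stat2, an interferon signalling factor, stood at 80.5 ± 33 TPM in WT and 43.2 ± 6.36 in KO, short of the test.

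Smaller shifts under LPS were called lower for ATF4 targets and amino acid metabolism (-0.09, adjusted p = 0.321 with an estimated correlation), for V-ATPase (-0.07, 0.412), for the NF-kB list (-0.11, 0.676) and for the unfolded protein response (-0.06, 0.676). In each pair the first number is the median and the second the adjusted p with an estimated correlation. With single libraries left out, the ATF4 median ranged from -0.13 (without KO_LPS_1) to -0.04 (without KO_LPS_4), and those of V-ATPase and the unfolded protein response from -0.15 and -0.11 (without WT_LPS_4) to -0.02 and 0.00 (without WT_LPS_3). The NF-kB median was -0.22 without KO_LPS_1 and turned to 0.11 without WT_LPS_3, and Il6 was its called member, a rise against the direction of the list. Neuron markers were higher, with a median of 0.71 for 11 genes and none called (adjusted p = 0.676 with an estimated correlation), and 0.42 without KO_LPS_3, the other library rich in pituitary hormone transcripts. Choroid plexus and ependymal markers were also higher (0.47, adjusted p = 0.685 with an estimated correlation, and 0.25 without WT_LPS_3) and erythroid markers lower (-0.71, 0.676 in the same order), with a median of 0.35 without WT_LPS_4. The lipid efflux list was called lower although its median was 0.04, its mean being -0.05 (adjusted p = 0.676 with an estimated correlation), and the median was -0.08 without KO_LPS_1. Called with smaller medians were branched-chain amino acid catabolism (0.12) and nucleotide synthesis (0.14), higher, and autophagy (-0.02), glycolysis (-0.14), antigen presentation (-0.13), B cell (-0.10), oligodendrocyte lineage (-0.22) and endothelial and mural markers (-0.16), lower. These 8 had an adjusted p of at least 0.465 with an estimated correlation. Leaving out 1 library turned the median of 5 of them. Antigen presentation and glycolysis ranged from -0.24 and -0.20 (without WT_LPS_4) to 0.04 and 0.02 (without WT_LPS_3), endothelial and mural markers from -0.38 (without WT_LPS_3) to 0.11 (without KO_LPS_2), autophagy from -0.06 (without WT_LPS_4) to 0.01 (without KO_LPS_2), and oligodendrocyte lineage markers from -0.63 (without WT_LPS_3) to 0.12 (without WT_LPS_1). The B cell median ranged from -0.24 (without KO_LPS_1) to -0.01 (without WT_LPS_2). Antigen presentation, autophagy, nucleotide synthesis and endothelial and mural markers were each called in 4 of the 8 fits that left out 1 library.

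Set side by side, the genes called in either treatment mostly pointed the same way. Of the 191 genes called under PBS, 91.6% had the same sign under LPS, and of the 93 called under LPS, 90.3% had the same sign under PBS. Across all 18724 genes, however, the effects correlated with a Pearson's r of 0.022 and a Spearman's rho of 0.070. Pearson's r was higher, though still low, in some other settings given below. These are values across genes, which are not independent replicates. Both comparisons called 27 genes in the same direction and 0 in opposite directions by limma. Of these, 20 were higher, where independent lists of these sizes would share 0.382, and 7 were lower, where they would share 0.101. Both comparisons use the same estimate of the spread of each gene, so their lists are not independent and chance could share more. The 7 lower genes were Cox6a2, Cd22, H2-Ob, Rcbtb2, Ptgfrn, Enpp1 and Tmem119. The higher ones included H2-DMa, H2-DMb2, Epha2, the ribosomal protein genes Rpl12, Rps18, Rps19, Rpl5 and Rps13, the ribosome assembly gene Ppan, and Rack1, a component of the small ribosomal subunit. Rcbtb2, Ptgfrn, Enpp1, Rps19, Rpl5, Rps13, Ppan and Rack1 were named after their values were seen.

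**Figure D4:**
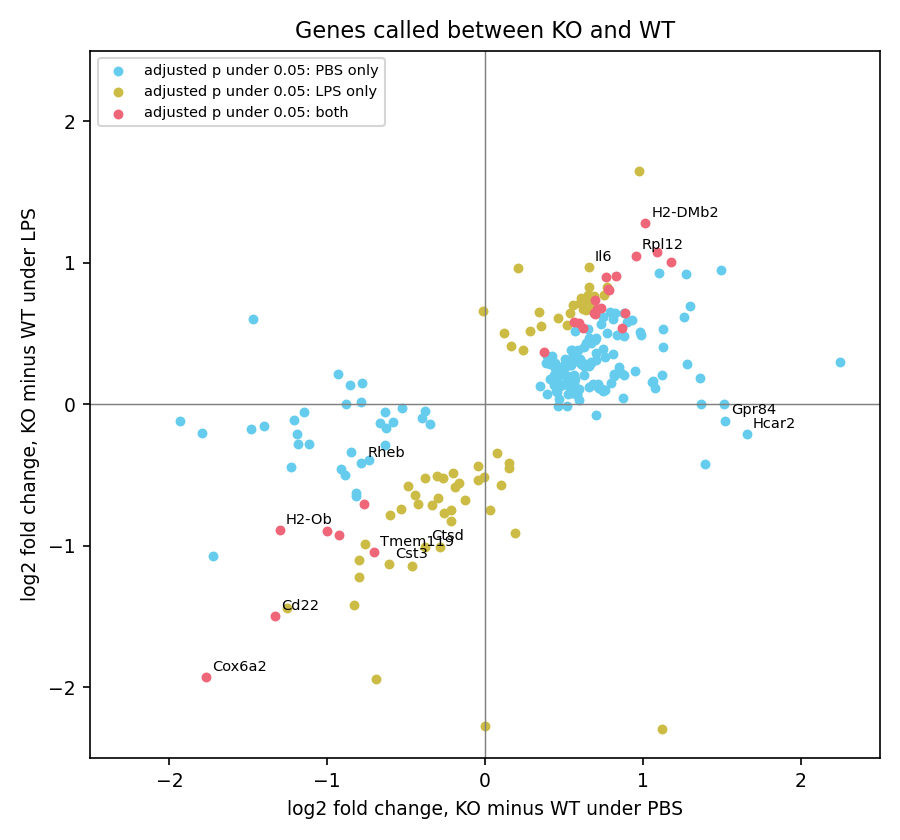
Log2 fold change of KO minus WT under PBS (horizontal) and under LPS (vertical) for the 257 genes called in either comparison, coloured by where they were called, with 8 genes beyond the axis limits of 2.5. The genes called in both lie in the lower left and upper right.

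LPS treatment of WT mice, which asks for the microglial response to endotoxin, went with large rises of acute-phase and inflammatory genes. Saa3, an acute-phase protein, rose from 0.637 ± 0.258 to 2192 ± 1300 TPM, Marco, a scavenger receptor, from 0.559 ± 0.611 to 420 ± 156 TPM, Acod1, the enzyme that makes itaconate, from 2.18 ± 2.5 to 286 ± 311 TPM, and Il1b from 23 ± 9.89 to 692 ± 463 TPM. Of 58 NF-kB and inflammatory mediators, 50 rose and 3 fell (median log2 fold change 2.19, adjusted p = 0.0962 with an estimated correlation). The 3 that fell were Tgfb1 (-0.37), Il6 (-0.45) and Tlr4, the LPS receptor (-0.51), and with median-of-ratios scaling they stood at -0.03, -0.14 and -0.18, not past the test. Interferon response genes rose in 47 of 59 cases (median 1.39, adjusted p = 0.342 with an estimated correlation), such as Cxcl10 (4.78), Oasl1 (2.87) and Gbp5 (2.87). Monocyte markers rose in 13 of 15 cases, with Treml4 (4.45), F10 (4.15) and Itgal (3.38) ahead (median 2.18, adjusted p = 0.0962 with an estimated correlation). By limma, 7866 genes were called, 1488 higher and 6378 lower, around a median of all genes of -0.28. Median-of-ratios scaling, which removed this shift, gave 5493 calls, 3022 higher and 2471 lower.

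Further groups were called in WT. Disease-associated microglia genes rose in 19 of 33 cases and fell in 4, with Lilrb4a (2.28) and Cybb (2.23) rising and Cd9 (-0.35) falling, though with median-of-ratios scaling Cd9 stood at -0.01, not past the test (adjusted p = 0.0962 with an estimated correlation). Ribosomal protein genes rose in 36 of 78 cases (median 0.37) and cell cycle genes in 11 of 48 (median 0.65, with Mki67 at 1.19, Pbk at 1.17 and E2f1 at 1.01), both with an adjusted p = 0.450 with an estimated correlation. Homeostatic microglia genes fell in 29 of 48 cases and rose in 2 (median -0.50, adjusted p = 0.693 with an estimated correlation), and this call was lost with median-of-ratios scaling (median -0.16, 13 lower and 5 higher). Upk1b (-1.81), Slc2a5 (-1.59), Gpr34 (-1.15) and Tmem119 (-0.99) fell, while Itgam (0.84) rose. Within antigen presentation, class I genes such as H2-Q7 (1.78) and H2-Q4 (1.48) rose and the class II genes H2-Ab1 (-1.34) and H2-Eb1 (-1.50) fell (adjusted p = 0.483 with an estimated correlation for the list). All 13 choroid plexus and ependymal markers fell, Kl by -2.11 and Dynlrb2 by -2.03 (median -1.99, adjusted p = 0.450 with an estimated correlation), as did 25 of 35 genes of the pyruvate dehydrogenase and TCA cycle list, Pdk4 (-1.60) and Pdk2 (-1.16) most (median -0.39, 0.450). That last call was lost with median-of-ratios scaling, where the median was -0.06 and 7 genes were lower. Branched-chain amino acid catabolism (median -0.50), autophagy (-0.33) and nuclear-encoded oxidative phosphorylation (-0.32) were called lower, and the last 2 stood at 0.00 and 0.02 with that scaling. Called higher were mitochondrially encoded genes (0.29), neutrophil (0.61) and T and NK cell markers (0.47), immediate early genes (0.25), glycolysis (0.19), and lipid efflux and storage (0.17). The neutrophil median was 0.32 without WT_PBS_904 and 1.17 without WT_PBS_914, and without WT_LPS_3 the medians of T and NK cell markers and of glycolysis were 0.31 and 0.02 and that of cell cycle genes 0.43 (likewise without WT_PBS_904). The immediate early median ranged from 0.17 (without WT_PBS_914) to 0.45 (without WT_PBS_913) and the lipid efflux median from 0.10 (without WT_PBS_914) to 0.28 (without WT_LPS_4), and that of mitochondrially encoded genes was 0.19 without WT_LPS_2. Border macrophage markers were called higher with a median of -0.26 (-0.46 without WT_PBS_914, -0.03 without WT_PBS_913) and a mean of 0.23, and astrocyte markers (-0.73) were not called. For these 10 called lists the adjusted p was at least 0.450 with an estimated correlation.

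Lysosomal genes went both ways in WT after LPS, with 17 rising and 21 falling of 78 and a median and mean of -0.03, the median ranging from -0.12 (without WT_PBS_914) to 0.02 (without WT_PBS_904). Camera placed the list above other genes (adjusted p = 0.713 with an estimated correlation), and with median-of-ratios scaling its median was 0.31. Acp5, a lysosomal phosphatase, rose by 3.74 and Ctsl, a cathepsin, by 0.78, and Cd164 fell by 1.37 on the log2 scale. Of the genes fixed in advance, Ctsb (0.48), Lamp1 (0.29) and Tnf (3.07) rose, Mtor (-0.48), Rptor (-0.59) and Tfeb (-0.33) fell, and Rheb stayed within its spread (-0.07). The falls of Mtor, Rptor and Tfeb should be read against the shift of -0.28 over all genes, as with median-of-ratios scaling they stood at -0.15, -0.26 and -0.01, not past the test, while Lamp2 (0.38) passed. The mTORC1 list was called lower (median -0.27, 0.05 with median-of-ratios scaling, adjusted p = 0.576 with an estimated correlation). Among the largest single falls were the Y-linked genes Ddx3y (-6.77), Eif2s3y (-6.25), Uty (-3.92) and Kdm5d (-3.89), and Xist (8.08) was among the largest rises. Bpifa1 (-4.91), Ighd4-1 (-4.62), Retnla (-4.15) and Resp18 (-4.07) also fell, and Cd5l (5.95), Ackr1 (5.88), Cxcl13 (5.62) and Hcar2 (5.46) rose. Resp18 is an endocrine gene whose PBS level was 83.6 ± 121 TPM and whose call was lost with median-of-ratios scaling (-3.85).

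In KO mice, much of the same change went with LPS, and again with the difference in Xist and Y-linked transcripts. Saa3 rose from 0.587 ± 0.738 to 1560 ± 614 TPM, Marco from 0.209 ± 0.284 to 531 ± 84.7 TPM and Il1b from 24.3 ± 3.21 to 530 ± 206 TPM. NF-kB and inflammatory mediators rose in 46 of 58 cases and fell in 3 (median 1.59, adjusted p = 0.132 with an estimated correlation), interferon response genes rose in 28 of 59 (median 0.90, 0.412) and monocyte markers in 13 of 15 (median 2.72, 0.132). Cell cycle genes rose in 32 of 48 cases, with Mki67 (1.83), Melk (1.69) and Birc5 (1.67) ahead (median 1.02, adjusted p = 0.412 with an estimated correlation). Homeostatic genes fell in 41 of 48 cases and rose in 1 (median -0.85, and -0.58 with median-of-ratios scaling, adjusted p = 0.412 with an estimated correlation), among them Upk1b (-2.46), Slc2a5 (-2.03), Gpr34 (-1.60) and Tmem119 (-1.33). By limma, 6494 genes were called, 1465 higher and 5029 lower, around a median of all genes of -0.22. With median-of-ratios scaling the calls were 4252, 2331 higher and 1921 lower, around a median of 0.00.

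Genes of the unfolded protein response list fell in 19 of 24 cases in KO, such as the endoplasmic reticulum chaperone genes Calr (-0.73), Canx (-0.71) and Pdia4 (-0.70), with a median of -0.49, and -0.23 with 8 lower with median-of-ratios scaling (adjusted p = 0.412 with an estimated correlation). Neutrophil markers rose in 10 of 18 cases, Trem1 (3.4) and Il1r2 (3.31) included (median 1.57, same adjusted p of 0.412 with an estimated correlation). Ribosomal protein genes rose in 33 of 78 cases, with Rps2 and Rpsa at 0.84, and choroid plexus markers fell in 12 of 13, with Kl at -1.74 and Ttr at -1.50 (adjusted p = 0.412 and 0.569 with an estimated correlation). Lysosomal genes fell in 34 of 78 cases and rose in 5 (15 and 15 with median-of-ratios scaling), and the list was not called (adjusted p = 0.109). In it Cd164 (-1.65) fell and Acp5 (4.61) rose, and Ctsd fell by 0.77 on the log2 scale. Tnf rose (1.59), Tfeb (-0.51), Mtor (-0.42) and Rptor (-0.75) fell, and Rheb had a log2 fold change of 0.30, not past the test. Cd5l (6.44), Acod1 (6.05), Cxcl13 (5.67), Ackr1 (5.49), Treml4 (5.37), Itgal (4.23) and F10 (4.65) rose, as did Gbp5 (2.60), Ifi204 (2.20) and Cxcl10 (2.12). Besides the Y-linked genes Ddx3y (-7.03), Eif2s3y (-6.25), Uty (-4.24) and Kdm5d (-3.85), falls included Retnla (-4.11), the haemoglobin genes Hbb-bs (-4.18) and Hba-a1 (-3.73), and Iglj3, which was listed at 0 in KO LPS. Xist rose (8.75), and Tgfb1 fell (-0.49). With median-of-ratios scaling the falls of Ctsd (to -0.50), Mtor (-0.16), Tfeb (-0.25), Tgfb1 (-0.23) and Ttr (-1.23) lost their calls, and Rheb (0.55), Lamp1 (0.43), Sqstm1 (0.29) and Ctsb (0.51) passed the test. Hbb-bs and Hba-a1 lost their calls there as well, but their log2 fold changes stayed between -4.68 and -3.41 and between -4.27 and -2.65 in every setting tried.

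Across genes, the LPS effects in WT and KO correlated with a Pearson's r of 0.689 and a Spearman's rho of 0.622. Both comparisons called 4857 genes in the same direction and 6 in opposite directions. Of these, 1005 were higher, where independent lists would share 116, and 3852 were lower, where they would share 1713. With median-of-ratios scaling, which removed the shift of all genes, 1795 were higher and 908 lower in both, where independent lists would share 376 and 254, and 12 went in opposite directions. Each comparison carries the same difference in Xist and Y-linked transcripts and in Gm23935, which adds to this overlap. The comparisons also use the same estimate of the spread of each gene, so their lists are not independent.

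**Figure D5:**
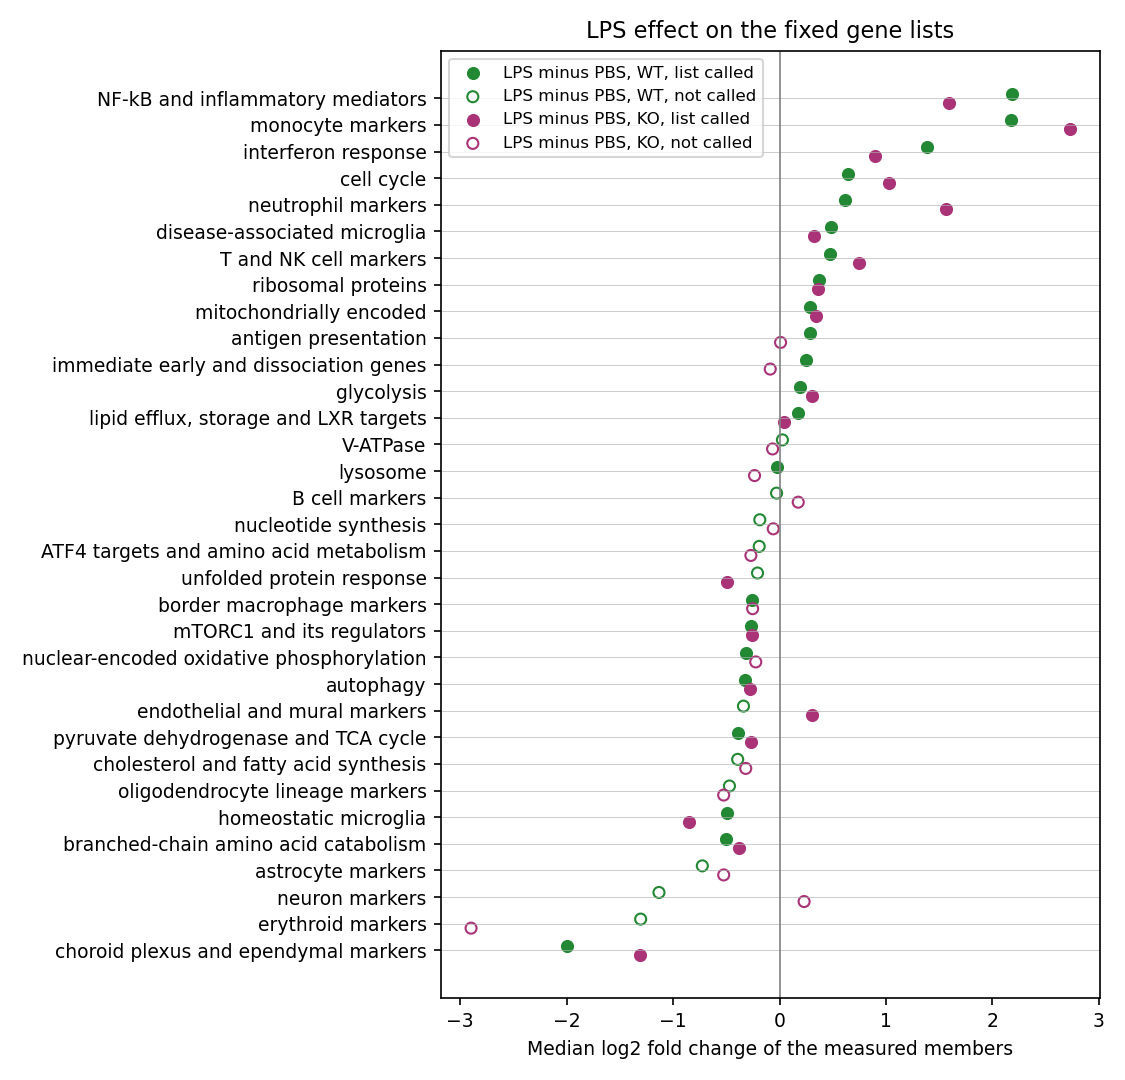
Median log2 fold change of the measured members of each of the 33 fixed gene lists, LPS minus PBS in WT (green) and in KO (purple), with filled points for lists called by camera at a preset correlation of 0.01. The NF-kB, monocyte and interferon lists lay highest in WT, with medians of 2.19, 2.18 and 1.39, and the choroid plexus list lowest at -1.99.

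Whether the LPS response differed between genotypes was tested by the interaction, the KO effect under LPS minus that under PBS. As Xist and Y-linked transcripts also parted the treatments, an interaction of a gene or list cannot be told apart from a difference between the sexes. No gene was called by limma: 0 of 18724 passed, 1780 had an unadjusted p under 0.05, and voom on recovered reads also called 0. Hcar2 came closest (-1.87, adjusted p = 0.0741), rising with LPS from 4.82 to 252 TPM in WT and from 17.3 to 218 TPM in KO. Next on the lower side were Mir1938 (-4.98, adjusted p = 0.188) and Nrros, a regulator of oxidative burst and TGF-beta activation in microglia (-0.64, adjusted p = 0.227). On the higher side were Cdkl2 (1.56), Cystm1 (1.37) and Cfap298 (0.93), each with an adjusted p of 0.227. Rheb (0.37), Tmem119 (-0.34), Ctsb (-0.24), Tnf (-1.47) and Il1b (-0.40) did not pass.

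As lists, 14 of 33 were called for the interaction with the preset correlation, 6 higher and 8 lower, and none with an estimated correlation. Homeostatic microglia genes had a median of -0.36, with 47 of 48 negative and 6 lower adjusted over the list alone (adjusted p = 0.871 with an estimated correlation), and Tmem173 at -0.54 had the smallest p among them. Interferon response genes had a median of -0.54 and Cxcl10 a value of -2.66 (adjusted p = 0.939 with an estimated correlation), and the median was -0.18 without WT_LPS_3. Lysosomal genes had a median of -0.20, with Pla2g15 at -0.56 (adjusted p = 0.939 with an estimated correlation), and the median was -0.10 without WT_PBS_914. The unfolded protein response had a median of -0.27, with Hspa5 at -0.58, and disease-associated microglia genes one of -0.32, which was -0.21 without WT_PBS_914 (both 0.871 as adjusted p with an estimated correlation). NF-kB mediators had a median of -0.28, with Gpr84 at -1.63 (adjusted p = 0.939 with an estimated correlation), and -0.12 without WT_LPS_3. The antigen presentation list had a median of -0.23 (adjusted p = 0.939 with an estimated correlation), and -0.10 without WT_LPS_3. Neuron markers were higher, with a median of 1.41 and Map2 at 1.41 (adjusted p = 0.871 with an estimated correlation), and 0.83 without WT_PBS_914.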

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

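The search for single outlying libraries and the test of the interaction were planned, but the limit of the gene search to groups with a TPM of at least 1 in every library was set after a first look. Within the LPS groups of 4 libraries, the gap between the most extreme library and its neighbour was divided by the range of the group and held against Dixon's critical value at the 95% level. Of 321 sets of values tested, 23 (7.17%) passed, where chance gives about 1 in 20. WT_LPS_4 accounted for 10, WT_LPS_3 for 6, KO_LPS_4 for 3, KO_LPS_1 for 2, and KO_LPS_2 and WT_LPS_1 for 1 each. The PBS groups, with 3 libraries, were not tested.

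WT_LPS_4 had the highest haemoglobin share (gap ratio 0.984, 0.0569% of TPM against at most 0.00108%) and the highest Gm23935 share (0.897, 15.4% against at most 5.21%). It had the lowest protein-coding share (0.941, 79.4% against at least 90.0%), ribosomal protein share (0.878, 4.21% against at least 5.51%) and ribosomal protein list mean (0.924). Canx (0.937), Rps6 (0.911), H2-DMb2 (0.861), Rpl32 (0.859) and the T and NK cell list mean (0.845) were lowest in it as well. Without WT_LPS_4, the ribosomal protein median under LPS was 0.48, and the list was still called at the preset correlation of camera (with all libraries and an estimated correlation it was not, adjusted p = 0.321).

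WT_LPS_3 was highest in WT LPS for Il6 (gap ratio 0.984), Stat2 (0.900), the NF-kB list mean (0.856) and the interferon list mean (0.831), and lowest for Kcnj9 (0.854) and Cdc42ep3 (0.834). KO_LPS_4 was highest in KO LPS for the lysosome list mean (0.934), Arsb (0.847) and Tmem119 (0.837). KO_LPS_1 was highest for the oligodendrocyte (0.967) and immediate early list means (0.879), KO_LPS_2 lowest for Mir1938 (0.831), and WT_LPS_1 highest for Tfeb (0.884). No cause of these single-library values was tested.

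The KO effect differed between treatments for 14 lists by the interaction test at the preset correlation, and for none with an estimated correlation, where the adjusted p was 0.871 to 0.945. Median interaction values were below 0 for lysosome (-0.20), unfolded protein response (-0.27), interferon response (-0.54), NF-kB (-0.28), homeostatic (-0.36) and disease-associated microglia (-0.32), antigen presentation (-0.23) and immediate early genes (-0.29). They were above 0 for branched-chain amino acid catabolism (0.13), cell cycle (0.50), monocyte (0.55), neutrophil (0.65), neuron (1.41) and endothelial and mural markers (0.55). Without WT_PBS_914 and KO_LPS_3, cell cycle, monocyte and neutrophil lists stood at 0.17, 0.27 and 0.29 and were no longer called. Without WT_LPS_3, the NF-kB, antigen presentation and interferon medians were -0.12, -0.10 and -0.18 and that of endothelial and mural markers 0.32 (0.90 without KO_LPS_2). Without WT_PBS_914, the medians were -0.10 for lysosome, -0.21 for disease-associated microglia, 0.83 for neuron, 0.15 for cell cycle, 0.16 for monocyte (0.82 without WT_PBS_913) and 0.18 for neutrophil markers (1.00 for the last without WT_PBS_904). Antigen presentation stood at -0.35 without WT_LPS_4, and the immediate early genes at -0.13 without KO_PBS_911 and -0.47 without KO_LPS_1. Of 100 splits of the libraries within treatments, 47 gave at least 14 lists, the highest other giving 21, so chance is not excluded for this count.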

How the results depend on the processing

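Alternatives that left out WT_PBS_914 and KO_LPS_3, removed Gm23935, left out short genes or used voom were chosen after seeing the data. Over all alternatives, the calls of named genes stayed on the same side in 4346 cases, gained a call in 65, lost one in 541 and reversed in 0. Cases on the same side include genes that were called in neither fit. The total also pools the LPS to PBS comparisons with the KO to WT comparisons. It therefore does not measure how stable the KO to WT calls are, for which the counts below are given. Causes were not tested, except that a fold limit and fewer libraries or genes act by construction.

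For KO to WT under PBS, 191 genes became 79 with no filter, 387 with quantile normalisation, 65 with no trend, 999 with library weights, 109 with only the 2 groups, 46 with a log2 fold change of at least 1, 303 without Gm23935 and 19 without WT_PBS_914 and KO_LPS_3, of which 17 were among the 191. Leaving out single libraries gave 8 to 50. The 13 lists became 0 with an estimated correlation, 7 without both pituitary-rich libraries, and 8 to 16 without single libraries.

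For KO to WT under LPS, 93 genes became 32 with no filter, 141 at a TPM of 5, 172 with median-of-ratios scaling (66 of them among the 93), 211 with quantile normalisation, 53 with mitochondrial, ribosomal protein and haemoglobin genes removed, 47 with no trend, 168 with weights, 20 with the fold limit, 163 without Gm23935, 241 with voom (53 higher, 188 lower) and 8 without both pituitary-rich libraries. A limma fit of only the 2 groups called 0 (1827 at an unadjusted p under 0.05) and a block by replicate number called 0 (1364). The numbers showed no pairing of libraries, as same-number correlations of -0.09 to 0.06 lay within the range of the other pairs (-0.092 to 0.094). So few pairs cannot exclude a pairing, and the block fit therefore stays as an alternative. Single libraries left out gave 18 to 99. The 21 lists became 0 with an estimated correlation, 12 without both pituitary-rich libraries, and 12 to 21 without single libraries.

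For LPS to PBS, 7866 genes in WT became 2514 with the fold limit, and stayed at 5803 to 7602 without single libraries. In KO, 6494 became 4252 with median-of-ratios scaling, 1495 with the fold limit and 4086 with voom, and 4613 to 6195 without single libraries. The lists, 22 in WT and 19 in KO, became 0 with an estimated correlation, and were 21 to 25 and 18 to 22 without single libraries.

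The interaction, with 0 genes, gave 3 with a pseudocount of 0.1 (Hcar2, Snord23, Mir1938), 1 with 5 (Gm23640), 1 with no filter and 1 with no trend (Gm23330), 2 with median-of-ratios scaling (Hcar2, Nrros), and 1 (Hcar2) each with quantile normalisation, weights, Gm23935 removed and short genes left out. Without both pituitary-rich libraries it gave 3 (Gm22858, Gm24465, Gm44450), and without single libraries 0 to 2. Its 14 lists became 0 with an estimated correlation, and 10 to 16 without single libraries. These genes were named after their values were seen.

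Rheb under PBS ranged from -0.84 to -0.72 without single libraries, and lost its call without both pituitary-rich libraries (-0.74, adjusted p = 0.0946). Under LPS it passed with median-of-ratios scaling (-0.51), quantile normalisation (-0.46) and voom (-0.50), and ranged from -0.51 to -0.35 without single libraries. Its adjusted p over the LPS alternatives ran from 0.028 to 0.592. The correlation of KO effects was 0.107 at a TPM of 5 and 0.132 without both pituitary-rich libraries, and that of LPS effects 0.769 and 0.723. Reads of 8.00 M in KO_LPS_4 limit low values there most.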

Other observations

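The tests of scaling, of length-matched genes and of the pituitary-rich libraries for the ribosomal pattern, of carry-over, of the genes around H2-Ob, of the class II genes by treatment and of B cells were chosen after the result was seen, as was the average KO effect. Other splits of the libraries were counted against each result. For KO to WT under PBS the 10 splits are too few for a share under 0.05: the real split (1 as large) called 191 genes and the highest other 4, and 2 gave 13 lists. Under LPS, only the real split, 1 of 35, gave as many as 93 genes, the highest other giving 2. Chance is unlikely for the genes but not excluded, as 35 splits can give no smaller share. The other splits also leave any real effect in the spread between libraries, which lowers their counts, and a fit of the compared groups alone called 0. For the lists chance stays open, as 5 of 35 reached 21 and the highest other was 26. For LPS to PBS, 1 of 35 splits reached 7866 genes in WT (highest other 3848) and 1 of 35 reached 6494 in KO (3158), with the same limits of the splits. Chance stays open for the lists there, with 5 of 35 in WT (22, highest other 24) and 6 of 35 in KO (19, highest other 21). For the interaction, the real count of 0 genes is reached by 100 of 100 splits by construction (highest other 59), so the splits say nothing about chance there. The other splits of the LPS comparisons that reached 3848 and 3158 genes mix treated and untreated libraries.

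The average KO effect over both treatments called 738 genes, 567 higher and 171 lower, by limma. Only the real split, 1 of 100, reached this, with 59 the highest other. The others were a random draw and share the limits of the splits above, so chance is unlikely but not excluded. Without WT_PBS_914 and KO_LPS_3, 248 were higher and 132 lower, 346 of the 738 among them. With median-of-ratios scaling 360 were higher and 285 lower, 525 among them. The excess of higher calls was thus smaller in both settings, and its cause was not tested. Rheb (-0.60), Cst3 (-0.87), Ctsd (-0.69) and Mpeg1 (-0.73) fell, and Ccnd1 (0.68) rose, all but Rheb chosen after their values were seen. By exact permutation of genotype within treatments, the ribosomal protein list had p = 0.00143, the smallest of 1400 arrangements (adjusted 0.0471), and ATF4 targets and interferon response each had p = 0.0114 (adjusted 0.126).

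Ribosomal protein genes were higher in KO in both treatments. The tables argue against scaling of the libraries, as the median of the list was at least 0.494 with median-of-ratios scaling, and against the pituitary-rich libraries as the cause, as it was at least 0.602 without them. A shift of genes as short and abundant was not seen in 230 genes of other kinds, with a median of at most 0.0658. Each lay within 5% of the length of a list gene and nearest in mean level. A first match of genes with a median length of 2604 nt, against 1776 nt in the list, gave at most 0.0757. These lengths join the exons of all isoforms and can exceed those of the mRNAs. The matched genes were also less abundant (median of mean log2 levels 8.83 against 9.29), so a shift of short or abundant mRNAs stays open. The mean difference was 0.29 for 14 other mRNAs with a terminal oligopyrimidine start (6 called higher, Eef1a1 at 0.56 and Npm1 at 0.47 among them) and 0.19 for 73 ribosome biogenesis factors (12 called higher), each with exact permutation p = 0.00143, the smallest possible, and p = 0.00286 and 0.0257 with median-of-ratios scaling. A wider change of the translation machinery is a candidate explanation, and what in the KO genotype it goes with was not tested, nor was RNA quality.

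WT_PBS_914 and KO_LPS_3 were the highest 2 libraries for 15 of 16 detected pituitary genes other than hormones, a list of 18 of which Foxl2 and Gata2 also had a median of at least 1 TPM elsewhere. Their hormone levels are given with the libraries above, as are Cga and Chga, which 3 further PBS libraries also held (Chga at up to 143 TPM, above the 120 TPM of KO_LPS_3) with Gh under 1 TPM, and Gh over Prl was 29.5 and 2.78. Carry-over from another library of the series is argued against, as the highest Gh elsewhere in it was 1.90 TPM. Reads from libraries outside the series were not examined. Pituitary tissue taken with the brain is a candidate source. Purification with magnetic beads is meant to remove such cells, but how far it did so was not tested. Markers of other cell types remained, such as the endothelial Pecam1 at 89.5 TPM in WT PBS. No other explanation, biological or technical, was tested.

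H2-Ob was lower and H2-DMa and H2-DMb2 were higher in KO under both treatments. A regional difference that changes many neighbouring genes stays open: 15% of the 40 genes nearest to H2-Ob had an unadjusted p under 0.05 for the average KO effect (95% interval 5.71% to 29.8%), against a median of 17.5% over windows on other chromosomes, and 7.5% of the nearest 40 when genes named before were left out. Over the genome, the 665 called genes other than ribosomal protein genes formed 44 adjacent pairs, where 10000 permutations gave a mean of 23.5 and at most 42 (p = 1e-04, the smallest they can give). The permutations treat neighbouring genes as independent, and overlapping genes can share reads. This excess therefore does not decide on a regional difference. A variant acting on these genes alone was not tested, and a change through the common class II regulator is argued against under PBS, as Ciita and 4 class II genes had a median of 0.0512 (upper 95% limit of their mean difference 0.608, against 0.89 for H2-DMa), and stays open under LPS, with a median of 0.389 (limit 1.40). For H2-Ob, fewer B cells could contribute and stay open. The 9 other B cell markers had a median of -0.295 or lower (exact permutation p = 0.0957, and 0.03 with median-of-ratios scaling). Cd79b fell (-0.70), but Bank1 rose (0.66). From WT to KO, Ighm went from 354 to 265 TPM, Ighd from 21.6 to 9.65 and Igkc from 110 to 111 under PBS. Under LPS they went from 181 to 115, 7.39 to 4.84 and 120 to 177. How far purification with magnetic beads removed B cells was not tested.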
